A study of Mus musculus with 2 samples.

How the data were processed

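The series holds 2 libraries of mouse day 5 motor neuron cultures, 1 anti-V5 ChIP library of a line with inducible Hoxc9-V5 and 1 WCE library. The ChIP labels describe a Hoxc9-V5 line, while the WCE labels describe an inducible Cdx2-V5 line made in the same Ainv15 parent, with FGF signalling applied in Cdx2 experiments, so the background may come from another line and treatment than the ChIP. Another WCE track that the deposited notes list was not analysed here.

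Reads of 36 bp were aligned to the mm8 genome with Bowtie 0.9.9.2, per the submitters' processing notes; the aligner's options are not given in the sources used here. The authors deposited one line per alignment, with a leftmost position and a count of other places of equal quality, per the values in the files. Each read was listed at 1 or 2 places: 25.5% of ChIP reads and 27.3% of WCE reads had 2. For the peak list, the authors counted ChIP reads at the summit and over the region, per the file headers, in whole numbers. Its deposited background hits are a signal, not counts: the authors multiplied background reads by a factor close to 0.44 and rounded them, as the spacing of the values shows. The authors' fold over background is the ratio of ChIP hits to scaled background hits, per the file headers and the values. The authors' score, by which the deposited list is sorted, runs from 1.8e-55 for the strongest peak to 0.00893; the file does not define it, and it was used only to rank peaks. The caller, its version and its options are not given in the sources used here. With single-place reads extended to 200 bp, the authors' ChIP counts equalled a recount in 73.4% of regions (93.7% within 1 read), and their background, divided by 0.44, equalled the count of this WCE library in 78.9% (97.2% within 1 read).

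Ratios were recomputed from the alignments. Reads listed at 1 place were used, at most 1 per position and strand, which removed 9.94% of the ChIP and 1.85% of the WCE reads, since copies of 1 fragment are not independent. Each read's 5' end was moved 100 bp towards its 3' side to stand for the fragment's middle. WCE was scaled by the ratio of reads outside the peaks (0.430). The ratio of ChIP to scaled WCE has exact 95% limits from the conditional binomial share, and shares have Clopper-Pearson limits. Where WCE had no read, a bound was computed against a floor of 3 reads; it leaves out the error of the ChIP count, so the exact lower limit, given beside it, can be lower. A peak passed the rule with a ratio of at least 5 and a lower limit above 1, and a ratio over no WCE read counted as above 5. Bins of 1 kb that touched no peak were held to the same rule with at least 20 ChIP reads. Chromosomes were compared in bins of 1 Mb with at least 200 WCE reads, with 0.5 added to each count before the log2 ratio. Precision is limited by the reads of both libraries: the median peak holds 13 ChIP reads and 1 WCE read, and few WCE reads widen the limits of the ratio.

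The peak list gives each peak's closest gene and signed distance to its start, up to 50 kb. Each peak therefore counts for 1 gene, and a gene is counted only where it is the closest gene of a peak. The sign was read as upstream when negative, since only that reading gives genes with several peaks a single start position. No annotation of mm8 was used here, so distances rest on these columns, gene bodies were not used, and the planned background of random positions for distances and the planned matching of random gene lists on gene length were not run. A RefSeq gene table on the assembly GRCm38.p6 served for names, for the genes of the random lists and for finding neighbours of Hox genes. It gave no distances of peaks. Of 941 names, 629 matched a symbol, 218 a synonym and 60 an accession, and 34 did not match. The Hox windows planned between the outermost genes of each cluster were replaced, after seeing the data, by windows of 100 kb centred on the Hox gene starts that the distances give. They were set against 10000 random windows with at least 100 WCE reads and against windows around the other peaks. Gene lists were set against 10000 random lists of the same size from 21031 protein-coding genes of the RefSeq table. Any of these that the authors' annotation lacks could not be the closest gene of a peak, which can lower the random rate. Lists without Hox neighbours left out 142 genes within 1 Mb of the Hox clusters, by the positions in that table. The values of 2 named genes are not reported here.

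For words, the sequences of ChIP reads within 100 bp of a peak centre were compared with those at 500 to 1000 bp, on both strands, for 10 words and their base-reversed forms. Exact limits take each read as independent; limits from 2000 draws of whole peaks with replacement were added after seeing the data. The reversed form of CAGCTG contains CpG, which is rare in the mouse genome, and is a poor control. ATTAAT, reversed from TAATTA, also contains TAAT and ATTA, and GACAGT, reversed from TGACAG, shares GACAG. Both are therefore poor controls too. Per peak, a word counts only where a read covers it; reads covered 87.3% of the peak windows.

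Chosen before the data were examined were the tests, the 14 gene lists, the words, the alternatives other than those described as added, and the rule for named genes: every Hox gene that is the closest gene of a peak within 10 kb, the 20 top peaks, and from each list the 3 genes whose nearby peak has the highest ratio. In that ranking a peak with no WCE read stands at its bound, which was settled after seeing the data and changed which Nkx2-2 peak is given. The alternatives were all reads counted, other scalings of WCE, reads not moved or moved 200 bp, windows of 200 bp either side of the centre, the higher-ranked 1359 peaks, ratios of at least 10, at least 40 reads per bin, bins at least 2 kb from peaks, merged peaks, other distances, lists without Hox neighbours, other centres and flanks for words, and bins of 250 kb. Alternatives added after seeing the data were WCE thinned to the ChIP depth and both places of reads listed at 2.

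The steps were tested on simulated data. Of peak windows with a true ratio of 2, 5, 10 and 20, the rule called 4.00%, 34.0%, 84.0% and 98.0%, and it called 0.318% of unchanged windows. Each simulated peak window had a WCE level of at least the mean over the peaks. These rates therefore do not cover peaks with fewer WCE reads, among them the 699 with none. In bins of 1 kb the rule called 18.0%, 84.0% and 100% at 5-, 10- and 20-fold. The bins given a fold had at least the mean WCE level of the bins used, so shallower bins are not covered. All planted words were found. Gene lists with a 10-fold and 20-fold excess passed the percentile in 58.0% and 94.5% of draws, and lists with no excess in none of 200. Analyses ran in Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.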

Results

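The study mapped where Hoxc9, a Hox transcription factor of the thoracic spinal cord, sits on chromatin in mouse motor neurons made from embryonic stem cells. Cells of the Ainv15 embryonic stem line were differentiated with retinoic acid and a hedgehog agonist, and a doxycycline-inducible Hoxc9 carrying a V5 epitope tag was switched on. Chromatin was precipitated with an anti-V5 antibody at day 5 and sequenced (ChIP). Unprecipitated whole-cell extract (WCE) of day 5 motor neuron cultures was sequenced as background. Each group holds 1 library, so no value has a replicate error and no p-value is given: ratios compare these libraries, not the conditions, and all intervals are 95% limits that cover counting error only. The ChIP library held 6193422 reads with a listed place on the genome, of which 4617130 had a single place. The deeper WCE library held 13409439 such reads, of which 9750389 had a single place. After each position and strand was counted once, 4158163 ChIP reads and 9570301 WCE reads remained.

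The first comparison asked where Hoxc9-V5 reads exceeded the WCE background. The authors listed 2719 peaks, which together covered 643701 bp of the mm8 genome with a median width of 224 bp. They held 1.04% of ChIP reads (1.03 to 1.05, exact Clopper-Pearson limits) and 0.0576% of WCE reads (0.0561 to 0.0591), an 18.3-fold excess over scaled WCE (17.8 to 18.8). The regions were selected by the authors for high ChIP over a background that matched this WCE library, so a high ratio over them follows from that selection and describes its size only. The strongest peak by the authors' score lay on chromosome 15 at 103133200 to 103133648, 5038 bp downstream of the start of Gpr84, which encodes a G protein-coupled receptor, with 172 ChIP and 8 WCE reads (50.0-fold, 24.8 to 118). The peak ranked 2, on chromosome 4 at 116828675 to 116829273, had no gene start within 50 kb and stood 71.1-fold above WCE (29.8 to 222). The peak ranked 3 lay 649 bp downstream of the start of Hoxc5, on chromosome 15 at 102842450 to 102842923, with 114 ChIP and 3 WCE reads (88.3-fold, 29.5 to 435). Among the top 20 peaks, 12 had no gene start within 50 kb. One of these, ranked 12 on chromosome 6 at 117372750 to 117373198, held 79 ChIP reads and no WCE read, at least 61.2-fold above WCE when WCE is set to a floor of 3 reads (exact lower limit 48.6). The other top peaks with a gene lay 758 bp downstream of the start of Hoxa4, 639 bp downstream of Hoxb4, 38177 bp upstream of Gpatch2l, 18637 bp downstream of Pck1, the gluconeogenic enzyme, 21786 bp upstream of Neil2, a DNA glycosylase, and 9094 bp downstream of Ubl4b. Their ratios were 232 (40.8 to 9272), 39.5 (16.3 to 125), 36.4 (16.1 to 102), 37.2 (15.3 to 118), 93.0 (24.9 to 781) and 34.4 (14.1 to 109), in that order.

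Of the 2719 peaks, 2366 (87.0%) had a ChIP to WCE ratio of at least 5 with a lower limit above 1. The share was 1343 of the 1359 higher-ranked peaks (98.8%) and 1023 of the 1360 lower-ranked peaks (75.2%). The median peak held 13 ChIP reads and 1 WCE read, and 281 peaks had a lower limit of 1 or less. Of the peaks past the rule, 566 had no WCE read, and for 146 of these the bound set by a floor of 3 WCE reads was itself below 5. Peaks were selected and ranked from the same reads, so these shares largely restate that selection and are no independent test of the peaks.

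The second comparison asked whether Hoxc9-V5 lay in the Hox clusters, the 4 arrays of genes that pattern the body axis. Peaks gathered at the genes of paralog groups 1 to 8: 19 of their 23 genes were the closest gene of a peak within 10 kb of the start, with 28 peaks in all. In groups 9 to 13, where Hoxc9 itself belongs, this held for 1 of 16 genes. Each peak was credited to its closest gene alone, so a gene beside a neighbour's peak can go uncounted. That gene was Hoxb9, whose peak at 126 bp upstream held 15 ChIP and 7 WCE reads, a ratio of 4.98 (1.91 to 14.4) that missed the rule of 5. It passed the rule when all reads were counted (5.79), when reads were not moved along their fragments (5.03) or with both places of reads listed at 2 (5.00), and stood at 1.62 with reads moved 200 bp and at 3.80 within 200 bp either side of the centre. No peak within 10 kb named Hoxc9, or Hoxa3, Hoxa7, Hoxb8 and Hoxd1 among the lower-numbered genes, as its closest gene. Counting only peaks past the rule left 17 genes of groups 1 to 8 and none of groups 9 to 13.

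Within the clusters, the highest ratios, with wide limits from few WCE reads, belonged to groups 4 and 5. The Hoxa4 peak lay on chromosome 6 at 52120250 to 52120748, with 100 ChIP reads and 1 WCE read. The Hoxb4 peak lay on chromosome 11 at 96135250 to 96135698, with 85 and 5 reads. Hoxb5 had a peak 3534 bp downstream of its start, at 96122950 to 96123373 on chromosome 11 (144-fold, 24.9 to 5783), and another 176 bp upstream (20.5-fold, 8.83 to 58.5). Hoxc4 had peaks 950 bp downstream (38.7-fold, 12.5 to 194) and 1477 bp upstream (34.1-fold, 10.9 to 172), on chromosome 15. The Hoxa5 peak 176 bp downstream stood at 21.3-fold (9.19 to 60.6), and its weaker neighbour 332 bp upstream had 4 ChIP reads and 1 WCE read. Hoxd4 had a peak 80 bp downstream (53.5-fold, 8.68 to 2202), and Hoxd3 had 3 peaks, the strongest 9288 bp upstream on chromosome 2 at 74535300 to 74535723 (33.1-fold, 12.3 to 126). Hoxc8 had a peak 7569 bp downstream (51.1-fold, 8.27 to 2110) and Hoxd8 one 6370 bp downstream (26.7-fold, 6.61 to 234). Ratios were lower at Hoxb1 (5.81, 1.68 to 25.4), Hoxa2 (6.13, 2.97 to 13.6, at the peak 390 bp upstream), Hoxc6 (4.26, 1.44 to 14.0) and Hoxa6 (2.66, 0.842 to 8.61). The other Hoxa2 peak, 193 bp downstream, stood at 10.1-fold (2.77 to 55.1). With reads moved by 200 bp, the peaks of Hoxb1, Hoxb2, Hoxb7 and the Hoxa2 peak 390 bp upstream missed the ratio rule. That of Hoxb2 also missed it with reads not moved and that of Hoxb1 within 200 bp either side of the centre (4.65), while those of Hoxc6, Hoxa6 and the weaker Hoxa5 peak passed with reads not moved. The Hoxc6 peak also passed with all reads counted (5.69), and the weaker Hoxa5 peak within 200 bp either side of the centre (13.9).

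In windows of 100 kb centred on the Hox gene starts, HoxA and HoxB held 12 peaks each, and HoxC and HoxD 8 each. These 40 peaks amounted to 100 per Mb, against 1.03 per Mb over the chromosomes. Of 10000 random windows, which could overlap the Hox clusters, 90.8% held no peak and the highest count was 8. The windows rest on genes that are the closest gene of a peak, so windows around the other peaks are the closer background: across 2672 of them the highest count was 6. Between the first and the last gene start with a peak, ChIP reads exceeded WCE 3.87-fold in HoxA (3.45 to 4.35), 2.63-fold in HoxB (2.40 to 2.88), 2.99-fold in HoxC (2.61 to 3.43) and 3.01-fold in HoxD (2.60 to 3.47). These edges were set by the peaks, since a Hox gene named by a peak farther out would have moved them, so the contrast between inside and outside is partly fixed by construction. In the 100 kb that begin 10 kb beyond these starts on the side of the higher-numbered genes there was no peak in any cluster, and the ratios were 1.08 (0.961 to 1.21), 1.14 (0.987 to 1.31), 1.10 (0.963 to 1.26) and 1.01 (0.878 to 1.16). In the 100 kb on the other side, HoxA had 2 peaks (1.59-fold, 1.37 to 1.84), HoxC had 6 (1.62-fold, 1.44 to 1.82), and HoxB and HoxD had none (1.34, 1.17 to 1.54, and 1.16, 0.969 to 1.39).

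**Figure D1:**
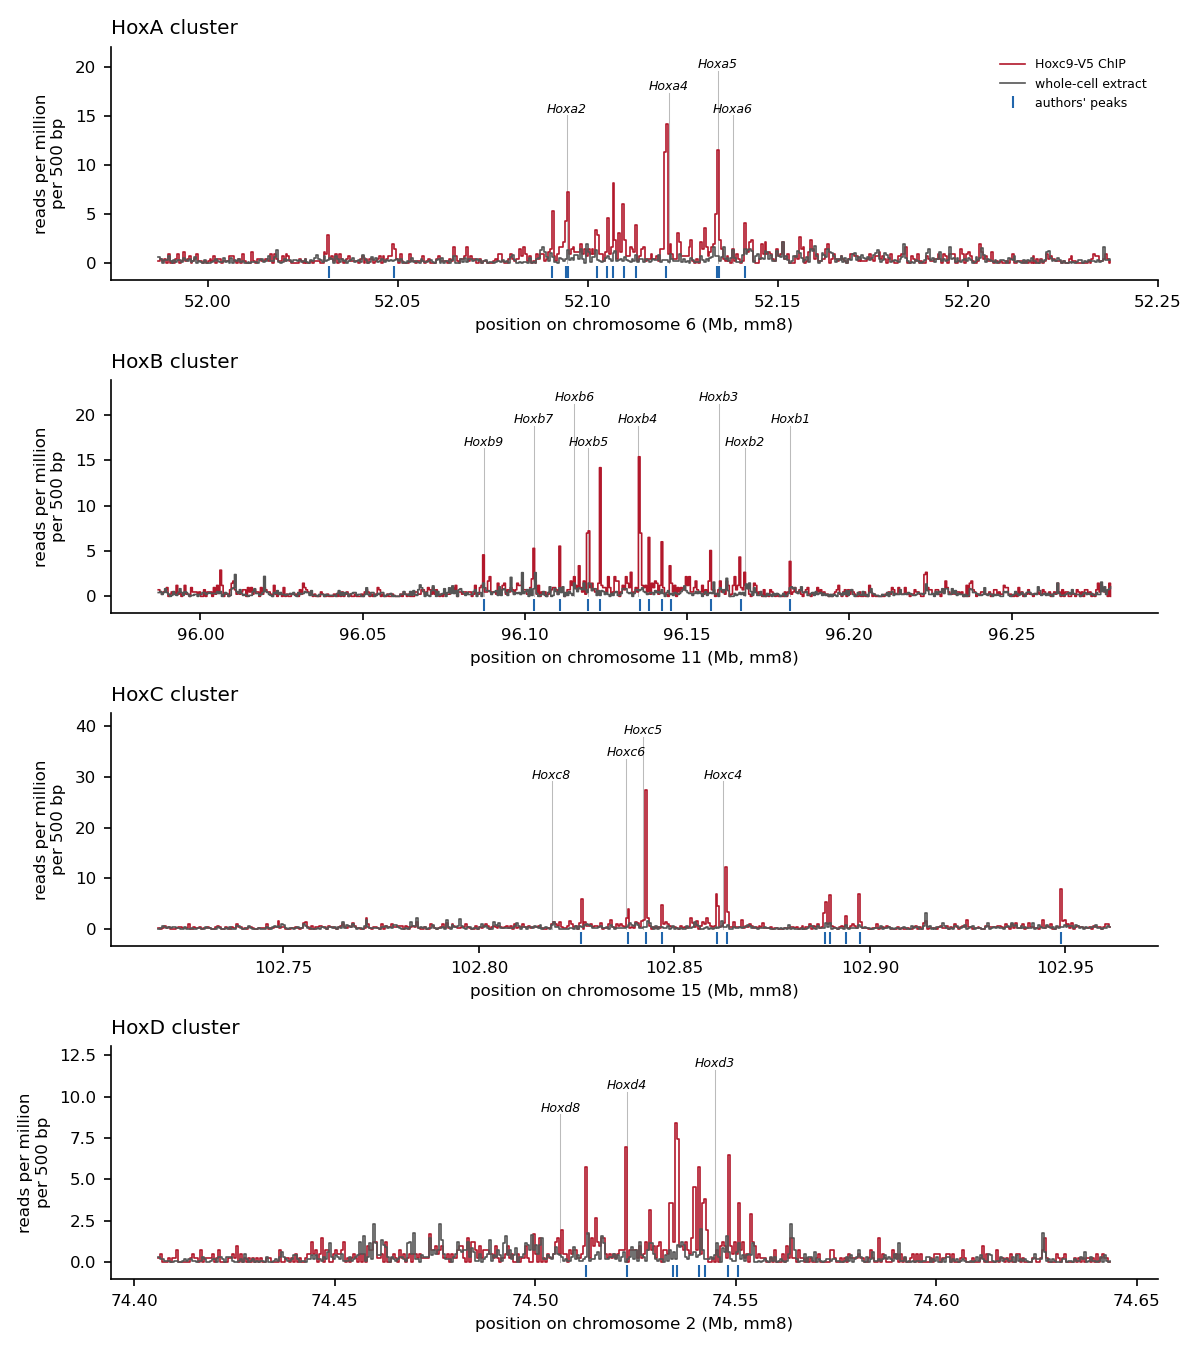
Reads in steps of 500 bp, scaled to 1000000 reads per library (vertical axis), along the 4 Hox clusters (horizontal axis, Mb of the mm8 genome) in the Hoxc9-V5 ChIP library (red) and the whole-cell extract (grey), with the authors' peaks as blue marks and the starts of reported Hox genes that are the closest gene of a peak within 10 kb as grey lines. ChIP peaks stand among the lower-numbered genes, and from 10 kb beyond the last marked start towards the higher-numbered genes (right of HoxA, left of the others) there is no blue mark, which the choice of edge partly fixes.

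The third comparison placed the peaks relative to gene starts. Most peaks were far from gene starts: 1603 of 2719 (59.0%, 57.1 to 60.8) had no gene start within 50 kb, and 703 (25.9%, 24.2 to 27.5) lay 10 to 50 kb away. Within 1 kb of a start lay 151 peaks (5.55%, 4.72 to 6.48), 104 of them upstream. A further 125 lay at 1 to 5 kb (4.60%, 3.84 to 5.45) and 137 at 5 to 10 kb (5.04%, 4.25 to 5.93). Peaks at gene starts had the lowest pooled ratio, 9.35 (8.52 to 10.3), against 14.5 (12.8 to 16.5) at 1 to 5 kb and 20.6 (19.8 to 21.4) with no gene within 50 kb. WCE reads were denser under them, at 17.9 per kb against 8.08 per kb under the other peaks and 3.63 per kb over the genome. The share within 1 kb was 3.31% (2.43 to 4.41) in the 1359 higher-ranked peaks and 7.79% (6.43 to 9.35) in the 1360 lower-ranked ones.

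The fourth comparison asked which gene groups had Hoxc9-V5 peaks within 10 kb of their starts, counting each peak for its closest gene. Of 21031 genes, 360 (1.71%) were the closest gene of one. Besides the Hox genes (20 of 39, against a mean of 0.674 in random lists of that size), 3 of the other 13 lists exceeded the 97.5th percentile of 10000 random lists. The share of random lists below was 100% for motor neuron identity, 99.93% for TALE cofactors and 98.38% for spinal progenitor and interneuron genes. No correction was made for the number of lists. Motor neuron identity genes had 4 of 15 (random mean 0.262): Mnx1, the motor neuron homeodomain factor, with a peak 5955 bp downstream (9.30-fold, 2.51 to 51.3), Nkx6-1 and Nkx6-2, homeodomain factors of ventral progenitors, with peaks 3833 bp downstream (9 ChIP reads and no WCE read, at least 6.97-fold against the floor of 3 WCE reads, exact lower limit 4.59) and 5258 bp upstream (10.5-fold, 2.17 to 99.5), and the proneural gene Neurog2. Cofactors of the TALE homeodomain class had 3 of 10 (random mean 0.176): Meis2 with a peak 138 bp upstream (5.58-fold, 1.83 to 20.2), Meis3 2949 bp upstream (13.9-fold, 3.10 to 128) and Tgif1 2263 bp upstream (12.4-fold, 3.55 to 66.4). No Pbx gene was the closest gene of one. Spinal progenitor and interneuron genes had 3 of 30 (random mean 0.529), among them the progenitor homeodomain genes Dbx1, with a peak 2285 bp downstream (27.9-fold, 4.13 to 1192) and Dbx2, with one 1589 bp downstream (25.6-fold, 3.72 to 1101). The peaks given here with a ratio were of low depth, between 9 and 16 ChIP reads. With reads moved by 200 bp, those of Mnx1, Nkx6-1, Nkx6-2, Meis2, Meis3, Tgif1 and Dbx1 missed the ratio rule.

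Axial patterning (2 of 15, 97.37% of random lists below), Notch pathway (2 of 15, 97.27%) and mesoderm and endoderm genes (2 of 16, 97.11%) stood just under the percentile. Their members were Cdx2, 1761 bp downstream (27.9-fold, 4.13 to 1192), and Sall4, 4804 bp downstream (53.5-fold, 8.68 to 2202); Notch1, 2874 bp downstream with 43 ChIP and 3 WCE reads (33.3-fold, 10.7 to 168), and Dll1, 6777 bp upstream with 19 and 0 reads (at least 14.7-fold against the floor, exact lower limit 10.8); Meox1, 7158 bp upstream (24.4-fold, 5.97 to 215), and Alb, 5343 bp downstream with 4 and 0 reads. Axon guidance genes had 2 of 28 (91.48% of random lists below), Efnb2 (44.2-fold, 7.02 to 1835) and Unc5b (12.4-fold, 3.55 to 66.4). Hedgehog pathway genes had 1 of 14 (78%), the ventral progenitor factor Nkx2-2, 1976 bp upstream with 25 ChIP reads and 1 WCE read (58.1-fold, 9.51 to 2386). Pluripotency genes had 1 of 12 (81.04%), Sox2, 7062 bp downstream with 11 and 0 reads (at least 8.52-fold against the floor, exact lower limit 5.83). The housekeeping list, a background of genes used by all cells, had 1 of 16 (76.22%), Eef1a1 (16.3-fold, 2.09 to 733). With reads moved by 200 bp, the peaks of Sox2, Alb and Eef1a1 (1.16-fold) missed the ratio rule. With reads not moved, that of Eef1a1 had no WCE read and stood at 3.10 against the floor. Retinoic acid pathway (0 of 15), glia (0 of 12) and motor column and pool genes (0 of 24) had none.

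The result depended on the distance allowed. Within 50 kb, 9 of the 14 lists exceeded the percentile, among them motor column and pool genes with 9 of 24 (random mean 1.01): Aldh1a2, Cdh11, Ebf1, Epha4, Etv4, Foxp1, Lhx1, Mecom and Nr2f2. Foxp1, a marker of limb-innervating motor neurons, had its peak at a signed distance of -27037 bp from its start, on chromosome 6 at 99155375 to 99155698, with 20 ChIP and 2 WCE reads (23.2-fold, 5.65 to 205). Aldh1a2, an enzyme of retinoic acid synthesis, had one 25949 bp downstream with 17 and 0 reads (at least 13.2-fold against the floor, exact lower limit 9.59). These genes were named after their values were seen. At 10 kb and at 50 kb, random lists were matched on size alone, not on gene length or on the distance to neighbouring genes. A gene with more room around it can be the closest gene of more peaks, and its part in each excess was not tested.

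**Figure D2:**
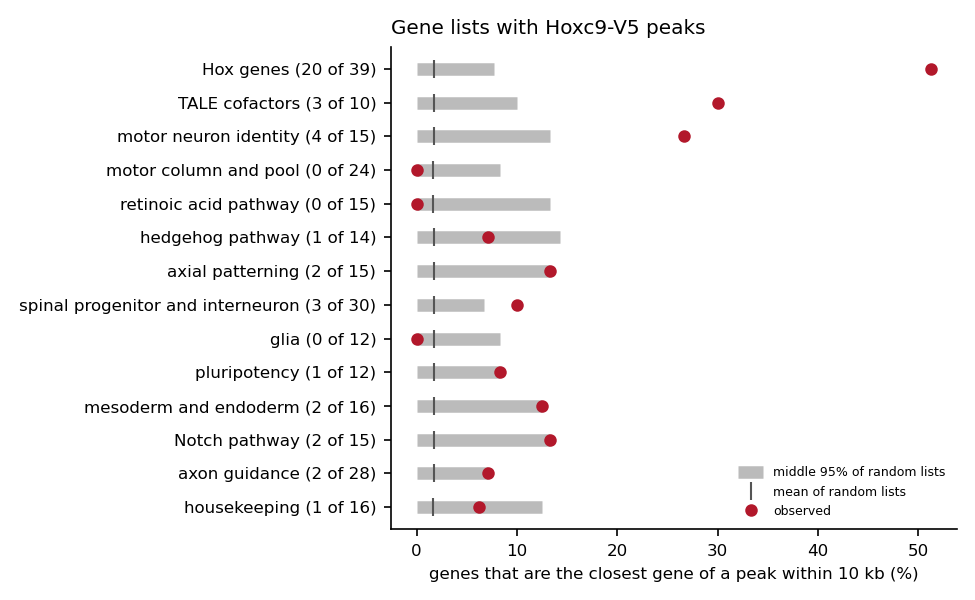
Percent of the genes of each list that are the closest gene of a Hoxc9-V5 peak within 10 kb of their start (red points, horizontal axis), with the mean (dark line) and the 2.5th to 97.5th percentile (grey bar) of 10000 random lists of the same size. Hox genes (51.3%), TALE cofactors (30.0%), motor neuron identity (26.7%) and spinal progenitor and interneuron genes (10.0%) lie right of their bars.

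The fifth comparison asked which DNA words were enriched in ChIP reads at the peak centres. The posterior Hox word TTTATGG and the Hox-Pbx word TGATTTAT were the most enriched of the 10 fixed words. The other fixed words of posterior Hox type, TTTATTG and TTTATTA, were enriched less (2.18 and 1.99). TTTATGG was present in 4.18% of the 33205 reads within 100 bp of a centre and 0.525% of the 10283 reads at 500 to 1000 bp, a 7.96-fold enrichment (6.06 to 10.7), whereas its base-reversed form GGTATTT stood at 1.25 (0.770 to 2.13). The Hox-Pbx word TGATTTAT was present in 2.91% and 0.311% of reads (9.35-fold, 6.58 to 13.7), and its reversed form TATTTAGT stood at 0.757 (0.335 to 1.87). TGATTGAT, a Hox-Pbx word of anterior type, was enriched 4.55-fold (2.89 to 7.56), against 0.495 (0.143 to 1.93) for the reversed form. Genome-wide, 0.360% of WCE reads held TTTATGG, 0.121% TGATTTAT and 0.0949% TGATTGAT. The Meis word TGACAG was enriched 2.05-fold (1.81 to 2.32; reversed 1.30, 1.11 to 1.53). TTTATTA reached 1.99 (1.52 to 2.64; reversed 0.860, 0.664 to 1.12), while TTTATTG reached 2.18 (1.77 to 2.72) with limits that overlapped those of its reversed form (1.73, 1.23 to 2.48). The E-box CATCTG stood at 1.37 (1.20 to 1.56; reversed 0.662, 0.504 to 0.877) and CAGCTG at 1.77 (1.54 to 2.05). The homeodomain core TAATTA stood at 1.29 (1.01 to 1.65) and its reversed form ATTAAT at 2.01 (1.56 to 2.61). Both words contain TAAT and ATTA, so ATTAAT is no neutral control and cannot decide whether the homeodomain core was enriched. CCACTAG, part of the CTCF site, was not enriched (0.942, 0.587 to 1.56). These limits count reads, several of which can cover 1 copy of a word. With whole peaks drawn at random in their place (2000 draws, a test added after seeing the data), the limits were 5.97 to 11.5 for TTTATGG and 6.52 to 14.6 for TGATTTAT. Those of TGATTGAT (2.68 to 9.73) then overlapped those of its reversed form (0.0517 to 2.76), and those of TAATTA (0.957 to 1.81) included 1.

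**Figure D3:**
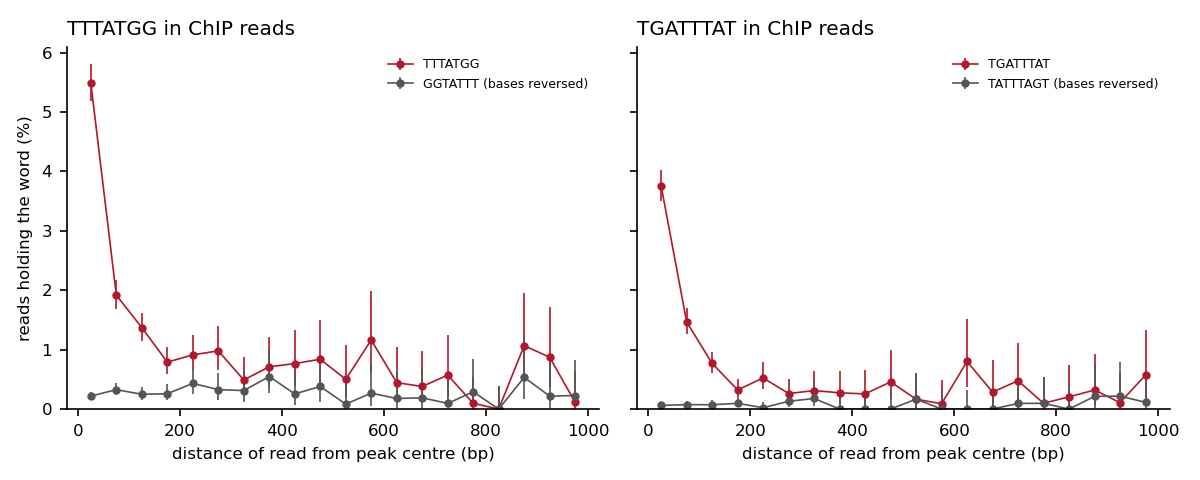
Percent of ChIP reads holding TTTATGG (left) or TGATTTAT (right) in red and its base-reversed form in grey (vertical axis), in steps of 50 bp of distance from the peak centre (horizontal axis, bp), with 95% Clopper-Pearson limits. In the first 50 bp, 5.49% of reads held TTTATGG and 3.75% TGATTTAT, against 0.219% and 0.0618% for the reversed forms.

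Either TTTATGG or TGATTTAT was read in 669 of 2719 peaks (24.6%, 23.0 to 26.3), and a reversed form in 46 (1.69%, 1.24 to 2.25). The share rose to 55 of the top 100 peaks (55.0%, 44.7 to 65.0; reversed 0 of 100). It was 18 of 36 (50.0%, 32.9 to 67.1; reversed 1) in peaks whose named gene was a Hox gene and 22 of 151 (14.6%, 9.36 to 21.2; reversed 2) at gene starts. Reads covered 99.5% of the windows of the top 100 peaks against 87.3% over all peaks, so part of the rise can come from coverage. In the Gpr84 peak the site was on the minus strand of chromosome 15 at 103133449 to 103133455, 18 bp from the centre, within CAGATTTATGGTCAG. The Hoxc5 peak held one at 102842656 to 102842662 (minus strand, AAAATTTATGGCCGC). The Hoxa4 peak held one on each strand of chromosome 6, at 52120469 to 52120475 (minus, ATTCTTTATGGCTCT) and 52120551 to 52120557 (plus, TAAATTTATGGGGGC). The Pck1 peak carried a joined word, CATCTGATTTATGGTC, with TGATTTAT at 172814673 to 172814680 on the minus strand of chromosome 2. The Cdx2 peak carried GCTCTGATTTATACGG, with TGATTTAT at 147615826 to 147615833 on the plus strand of chromosome 5. Gene parts (exon, intron, UTR) at these sites were not assigned, since no annotation of mm8 was used here.

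Outside the peaks, 42 of 2627418 bins of 1 kb had at least 20 ChIP reads and a ratio of at least 5. With the libraries exchanged the count was 2244, and it fell to 78, against 47 for ChIP, once WCE was thinned to the ChIP depth. By chromosome, the median log2 ratio of ChIP to scaled WCE outside peaks stayed within 0.06 of 0 on chromosomes 1 to 19 and X, with the largest departure on chromosome 13 (0.06). Chromosome Y stood at -1.12 (quartiles -1.14 and -1.04 over 3 bins of 1 Mb), with 582 ChIP and 2834 WCE reads, a ratio of 0.477 (0.436 to 0.522).

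**Figure D4:**
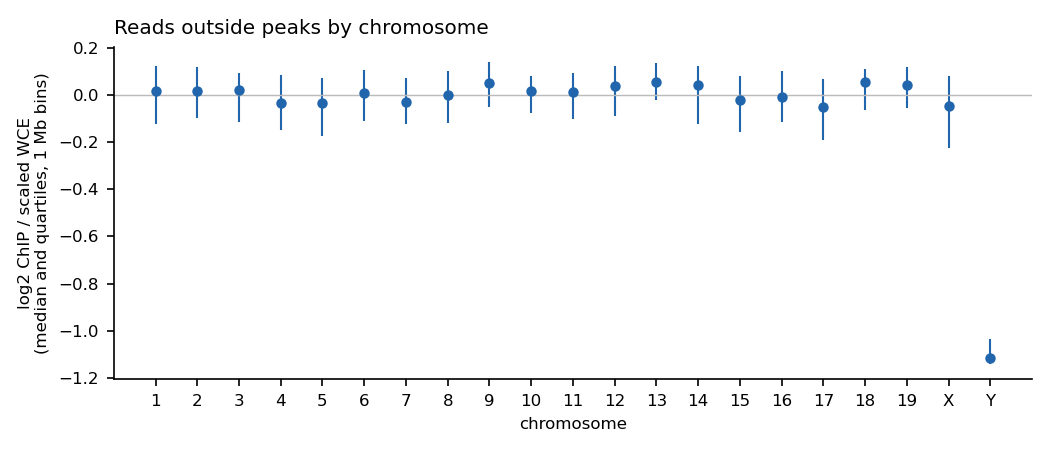
Log2 ratio of ChIP to scaled WCE reads outside peaks (vertical axis) per chromosome (horizontal axis), as the median (points) and quartiles (lines) over bins of 1 Mb. Chromosome Y lies at -1.12 and all other chromosomes within 0.06 of 0.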

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

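All tests of explanations in this part were chosen after the results were seen.

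Outside the authors' peaks, 42 bins of 1 kb stood at least 5-fold above WCE with 20 or more ChIP reads, in data that the peak comparisons do not use. At equal depth such bins were no more numerous than bins high in WCE, as the counts with the libraries exchanged show. They held between 20 and 28 ChIP reads. The highest read count was on chromosome 4 at 153190001 to 153191000 (28 ChIP and 12 WCE reads, 5.42-fold), and 1 bin lay in HoxA, on chromosome 6 at 52130001 to 52131000 (21 and 4 reads, 12.2-fold), and 1 in HoxD, on chromosome 2 at 74539001 to 74540000 (25 and 10 reads, 5.81-fold). These bins were singled out after their values were seen.

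With the libraries exchanged, 2244 bins stood above the rule, far more than the 42. After WCE was thinned at random to the ChIP depth, 78 remained, against 47 for ChIP, so the deeper WCE library accounts for most of the gap. No biological explanation was tested for the rest.

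Chromosome Y was lower in ChIP than in WCE. In 31 bins of 50 kb with at least 50 WCE reads its median log2 ratio was -1.05. Over all Y reads used, with no such minimum, the log2 ratio was -1.07 (-1.20 to -0.938). After subtracting the level of bins on chromosomes 1 to 19 with the same GC percent, the median over the bins was -1.06, which argues against GC content. In the 11 Y bins with the smallest share of reads listed at 2 places the median was -1.15. The median share of such reads was 75.3% in Y bins, 51.9% in X bins and 28.4% in bins of chromosomes 1 to 19. X bins had a median log2 ratio of -0.0132, so a share of that size came without a drop. The 11 bins are low only among Y bins, and the X share is smaller than that of Y, so neither can decide on reads with several places. All 31 bins spread over an interquartile range of 0.512, within the 0.317 to 0.724 that counting error alone gives at 1 level. Fewer copies of the whole chromosome in the ChIP culture would give this too, as a hypothesis. With a median of 15 ChIP reads per bin that range is wide. Its power to reveal a loss of only part of the chromosome was not tested. The labels describe different inducible lines for the libraries, and a gain in the WCE culture stays open too. In the bins kept, the median WCE count was 73 on Y and 69 on X, and the median ChIP count 15 and 30. The minimum of 50 WCE reads lifts the WCE medians where depth is low, so these values are not copy levels.

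Peaks at gene starts had a lower pooled ratio (9.35) than peaks with no gene within 50 kb (20.6). WCE reads were denser at gene starts, at 17.9 per kb against 8.08 under other peaks, which by itself lowers the ratio. Whether weaker ChIP signal adds to this cannot be told. ChIP reads above the scaled WCE level per peak were 0.892 times those of other peaks (0.745 to 1.07), an interval that includes both 0.8 and 1. That value counts reads per peak and makes no allowance for peak width. Capture of open chromatin without any Hox site is argued against as the whole cause: TTTATGG or TGATTTAT exceeded its reversed forms by 13.2 percentage points at gene starts (7.28 to 19.9). Such capture at part of the starts stays open, since this excess was 10.2 points smaller than elsewhere (3.30 to 16.2), while the ratio of words to reversed words was 11 (2.70 to 96.5) against 14.7 (10.8 to 20.4), with overlapping limits. Sites in the peaks at the starts of Hoxc5, Hoxa4, Hoxb4, Hoxc4, Hoxd4, Hoxc6 and Hoxb9 are part of the excess at gene starts. The excess at starts outside the Hox genes was not measured. No other biological explanation was tested.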

How the results depend on the processing

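The alternatives with both places of reads listed at 2 and with thinned WCE were chosen after seeing the data; the others were planned. The share of ChIP reads in peaks moved to 1.08% with all reads counted, 0.919% with reads not moved, 0.775% with reads moved 200 bp and 0.706% with both places of reads listed at 2. The ratio over all peaks moved to 19.01 with all reads counted, 16.0 with reads not moved and 14.4 with reads moved 200 bp. Bins outside peaks past the rule rose to 109 with all reads counted and 87 with both places, and fell to 0 at 40 ChIP reads or more, by that minimum itself. The count of peaks past the ratio rule stayed between 1755 (reads moved 200 bp) and 2493 (200 bp either side of the centre) over settings that keep all peaks and the ratio of 5; restricting to the 1359 higher-ranked peaks left 1343 by construction. The share of peaks within 1 kb of a gene start was 3.31% in the higher-ranked peaks, and 10.2% lay within 5 kb. Gene lists above the percentile numbered 9 within 50 kb, 7 in the higher-ranked peaks and 7 with peaks past the ratio rule, against 4. Within 50 kb these added motor column and pool (9 genes), retinoic acid (3), hedgehog (3), axial patterning (4) and axon guidance (7). Axial patterning (2 genes) also passed within 5 kb and, with Notch pathway (2), in the higher-ranked peaks, with peaks past the ratio rule and without Hox neighbours. Axon guidance (2) passed in the higher-ranked peaks and mesoderm and endoderm (2) with peaks past the rule. The TAATTA ratio fell to 1.26 in the higher-ranked peaks, where its limits include 1, as fewer reads would also give. The CCACTAG ratio, not distinguishable from 1 in the reported setting, turned to 1.22 against a flank of 1000 to 2000 bp and 1.19 in the higher-ranked peaks. Where no cause is named, the cause was not tested. The 40 peaks of the Hox windows became 30 in the higher-ranked peaks, 35 past the ratio rule and 36 after merging, and chromosome Y stood between -1.12 and -1.02. Of 66 named peaks, 19 changed their side of the ratio rule in some setting, 15 of them falling below it with reads moved 200 bp. Depth limits the ratios of single peaks, whose median is 13 ChIP reads and 1 WCE read. No paired analysis was possible because each group holds 1 library.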

Other observations

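The tests in this part on 8-base words, on dense windows and on strand were chosen after the data were seen.

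Outside the Hox clusters, which were the 4 densest windows of 100 kb, the next densest held 6 peaks on chromosome 4 at 153364286 to 153464285, near Prdm16, which encodes a zinc-finger transcription factor. Its strongest peak with a named gene lay 32565 bp downstream of the Prdm16 start, at 153447875 to 153448173, with 30 ChIP and 3 WCE reads (23.2-fold, 7.23 to 119). Windows with 5 peaks included those near the zinc-finger genes Zfp503 on chromosome 14 and Zfp608 on chromosome 18, those near Ttc30a1 and Tmem53, and that near Skap2, whose window at 51840791 to 51940790 on chromosome 6 lies beyond the lower-numbered end of HoxA.

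Several Hox peaks held TTTATGG on both strands a few bases apart. In the Hoxb4 peak the pair lay on chromosome 11 at 96135481 to 96135487 (minus, AAAATTTATGGGCGA) and 96135490 to 96135496 (plus, AATTTTTATGGCCTA). In the Hoxc4 peak it lay on chromosome 15 at 102863363 to 102863369 (minus) and 102863371 to 102863377 (plus), in the Hoxb5 peak on chromosome 11 at 96123104 to 96123110 (minus) and 96123117 to 96123123 (plus), and in the Hoxc6 peak on chromosome 15 at 102838127 to 102838133 (plus) and 102838136 to 102838142 (minus). How often such pairs arise by chance was not tested.

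Words of 8 bases were searched without a preset list on the 1382 peaks of the odd-numbered chromosomes and measured on the 1318 peaks of the even-numbered ones. CATAAATC (other strand GATTTATG), which overlaps both fixed words, was enriched 15.5-fold at the centres there (8.37 to 32.6), ATAAATCA (TGATTTAT) 11.2-fold (6.59 to 20.6) and ATTTATGG 8.91-fold (5.24 to 16.4). GCAGTAAA (TTTACTGC), a word outside the fixed set, was enriched 3.59-fold (1.99 to 7.12). Its 135 centre reads lay in 44 peaks, and with whole peaks drawn at random the limits were 1.85 to 8.81. Drawn in that way, the limits were 8.51 to 42.6 for CATAAATC, 6.55 to 25.03 for ATAAATCA and 4.87 to 21.7 for ATTTATGG. CGTAAATC (GATTTACG) was read 83 times at the centres, in 27 peaks, and not at all in the flanks, at least 8.82-fold against a floor of 3 reads (exact lower limit 7.02, counting reads).

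The ChIP to WCE ratio outside peaks followed GC content in an arch: the median log2 ratio of 50 kb bins was -0.35 at 35% GC, 0.16 at 46% and -0.49 at 58%. Reads listed at 2 places lay on the minus strand in 27.5% of ChIP and 29.4% of WCE cases, against 50.0% of reads listed once in both libraries.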
